A study of Mus musculus with 6 samples.

How the data were processed

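The series holds 6 single-colour Agilent arrays of total RNA labelled with Cy3, 3 from 4T1.2 cells with the base vector and 3 from 4T1.2 cells with Irf7. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, RNA was taken up on silica columns with a DNase step and amplified into labelled cRNA from 0.2 ug. Per the submitters' processing notes, the scans were read with Agilent Feature Extraction 9.5.3.1.

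Per the file headers, the deposited scanner files give each spot's intensity on a linear scale, background-subtracted and detrended within the array and not scaled between arrays (the processed signal), with the raw mean intensity and local background beside it. The authors also deposited a value table. Each of its columns was identical to the processed signal of the same array (largest absolute difference 0), so its scale is linear and it is neither centred nor scaled between arrays; its column medians were 56.5 to 79.0. It served as the alternative without scaling. The arrays held 45018 spots, of which 1639 were controls and were left out, as were 111 to 121 spots per array marked as non-uniform or as outliers. A single spot was saturated, on 1 array. The 75th percentile of the processed signal was 1148 to 1458. Per the file headers, base-vector replicate 1 and all 3 IRF7 arrays shared slide 1 and scan 1, and base-vector replicates 2 and 3 were on slide 2 and scan 2. Coordinates are those of the files, on mm7.

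Spots of a probe were averaged, giving 41174 probes. The accession of 22951 probes was matched to the gene table of the reference (assembly GRCm38.p6, used for names only), 6659 more matched by symbol and 3109 by an older symbol, and 8455 kept the name in the files. Log2 of the processed signal minus each array's 75th percentile was the level tested. Probes well above background on at least 3 of 6 arrays were kept (23518), and the probe with the highest mean signal stood for each gene (15414 genes); other probes are given for some named genes. The test was limma's lmFit and eBayes (limma 3.58.1, R 4.3.3) of IRF7 against base vector over all 6 arrays with no block, with Benjamini-Hochberg adjustment and a threshold of 0.05, with 4 residual and 1.63 prior degrees of freedom. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 read the files and drew the plots.

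Where a probe was not well above background on any array of a group, the fold is a bound: the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal well above background and the probe's own signal. The gene lists, the tests between the groups and of the lists, and the rule for naming genes were fixed before the data were examined. The rule named Irf7, the 12 largest rises and 12 largest falls among genes past the threshold whose groups did not overlap (clone and locus names left out), up to 4 members of each list with the smallest p, and the interferon and interferon regulatory factor families. Of the genes this rule chose, 3 are not reported here, though they count in their lists. The 21 lists were antiviral interferon-stimulated genes, interferon genes, interferon regulatory factors, interferon sensing and signalling, MHC class I, MHC class II, natural killer and T cell ligands, cytokines and chemokines, NF-kB, cell cycle, p53, epithelial, mesenchymal, bone metastasis, hypoxia, stress response, cholesterol synthesis, ribosomal and housekeeping genes, and markers of myeloid cells, lymphocytes, and fibroblasts, endothelium and fat. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, and with an estimated correlation and fry as alternatives.

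On simulated data drawn from these arrays, 50 genes were changed at each size among 15411. The test called 38% at a log2 change of 0.25, 74% at 0.5, 78% at 1 and 94% at 2. All estimates had the right sign, with 10 false calls, and with no gene changed it called 0. In the real data 61.2% of genes passed. The adjusted threshold depends on that share, so the simulated rates do not describe the real fit. The alternatives were normexp background correction with an offset of 50, quantile normalization, median centring, unscaled values, no filter or a stricter filter on dim probes, other probe rules, eBayes with trend and robust, slide as a fixed or random block, slide 1 alone, replicate number as a block, each array left out in turn and, added after the data were seen, the loss of chromosome 7 genes.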

Results

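The measurements were single-colour expression arrays of 4T1.2 cells, a mouse mammary carcinoma line derived from 4T1 that spreads to bone. The cells had been transduced with the pMSCV retroviral vector carrying Irf7, a transcription factor that drives type I interferon genes, or with the empty base vector. After puromycin selection, single cells were cloned and several clones were pooled, so each group is a pooled population. The 2 groups had 3 arrays each, from 3 independent experiments per the series' design text. On each array 43379 spots carried mouse probes, and 54.3 to 59.7% of them were well above background (54.3 to 56.8% in the base-vector arrays and 56.8 to 59.7% in the IRF7 arrays). After the dim probes were left out, 15414 genes were tested. The number of arrays limits the precision, and the p-values measure the spread between these cultures of 1 pooled population per group.

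The introduced gene was examined first. The probe for Irf7 (A_51_P421876, mouse build mm7, chromosome 7, positions 137682028 to 137682378) read processed signals of 246, 195 and 210.5 in the base-vector cells and of 4486, 4963 and 5012 in the IRF7 cells. On the log2 scale relative to each array's 75th percentile, the means were -2.41 ± 0.08 (SD, n = 3) and 1.87 ± 0.03 (SD, n = 3). Irf7 was therefore 19.4-fold higher in the IRF7 cells (log2 change 4.28, SE 0.049, limma adjusted p = 3.08e-07). The log2 change was 4.19 with slide as a block and within slide 1, the only slide that held both groups. Slide 2 held base-vector arrays only, so both fits take the log2 change from the IRF7 arrays and base-vector replicate 1. Here and below, their equal log2 changes are therefore 1 check, not 2. The probe of 60 bases spans 351 bases of the genome, so its sequence is split between exons, and it was the only Irf7 probe. It cannot separate the vector's transcript from the cell's own.

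**Figure D1:**
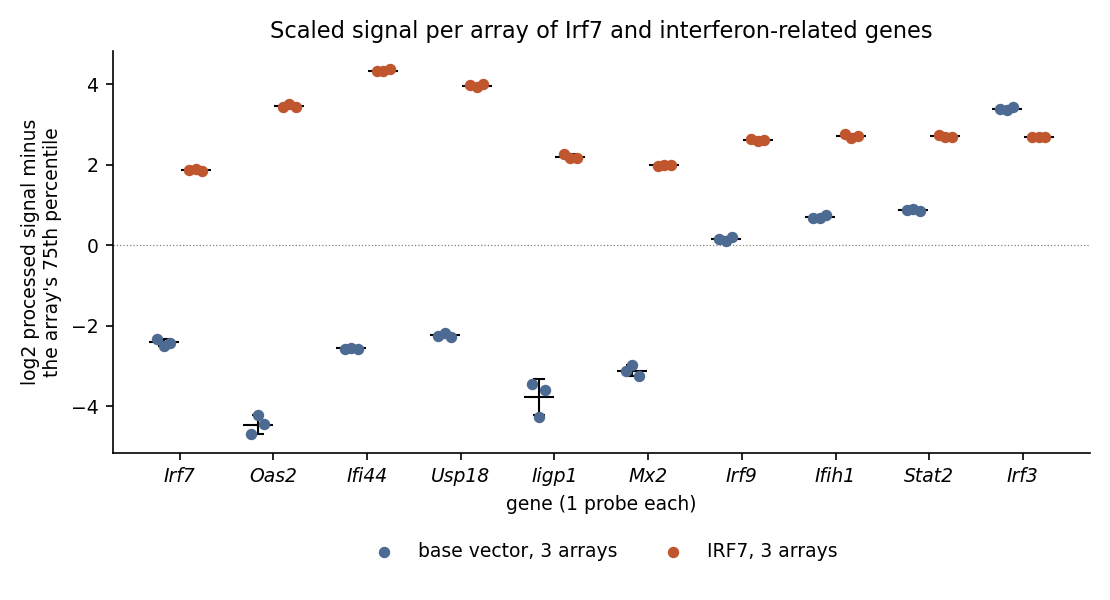
Log2 processed signal minus the array's 75th percentile for Irf7 and 9 interferon-related genes, 1 probe each, with points for the 3 base-vector arrays (blue) and the 3 IRF7 arrays (orange) and bars for the mean ± SD. Irf7 rises from -2.41 to 1.87 and Ifi44 from -2.56 to 4.33, while Irf3 falls from 3.39 to 2.69.

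The IRF7 cells differed most clearly from the base-vector cells in antiviral genes that interferon induces. Of 59 tested members of that list, 58 rose, 51 of them at least 2-fold, and none fell. The median member was 4.52-fold higher (log2 change 2.18), and 58 members also rose when adjusted over the list alone. Ifi44 was 119-fold higher (log2 change 6.89, SE 0.029), and Usp18, which removes the ubiquitin-like protein Isg15 from its targets, was 73.4-fold higher (adjusted p = 6.45e-08). The oligoadenylate synthetases, which sense double-stranded RNA, included Oas2 at 240-fold (7.90, SE 0.12) and Oas3 at 52.1-fold (5.70, SE 0.031). A second probe read a log2 change of 3.38 for Oas3 and of 5.07 for Ifi44, where it was above background on 1 base-vector array, and was at least 4.77-fold higher for Oas2, where no base-vector array was above background. The interferon-inducible GTPase Iigp1 rose by 5.96 (SE 0.22), the antiviral GTPase Mx2 by 5.10 (SE 0.069) and Zbp1, a sensor of left-handed nucleic acid, by 3.66 (SE 0.028). Ifitm1 did not pass, at 0.12 (adjusted p = 0.143). Against all other genes the list stood higher in limma's camera test (adjusted p = 2.83e-27). That call was lost where the correlation between genes was estimated from these arrays (adjusted p = 0.368 with an estimated correlation). With slide as a block, and so within slide 1, the median log2 change was 2.15.

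Interferon beta itself was detectable in the IRF7 cells. Ifnb1 was not well above background on any base-vector array and was so on all 3 IRF7 arrays, at least 2.57-fold higher. Its fitted log2 change was 3.33 (limma adjusted p = 1.84e-06), and 1.03 with normexp. That p tests the fitted change, whose base-vector signals lay near the floor of the arrays, and not the bound. Of 15 interferon genes on the array, 7 were not well above background on any array and 5 could be tested. Ifnab, an alpha interferon, rose by 0.54 (SE 0.15, adjusted p = 0.0211), but by 0.20 with slide as a block and within slide 1 and by 0.30 with a model-based background correction (normexp) whose offset of 50 shrinks differences between dim signals, and leaving out any array except base-vector replicate 1 ended its call (adjusted p = 0.0569 to 0.0633). Ifna13 (0.26, adjusted p = 0.106), Ifna9 (0.02, adjusted p = 0.749) and Ifnz (-0.05, adjusted p = 0.297) did not pass. A second Ifnz probe read -0.73, with SDs of 1.60 in the base-vector and 1.24 in the IRF7 arrays. That probe was above background on 2 base-vector arrays and 1 IRF7 array, so it decides nothing. Without base-vector replicate 1, Ifna13 passed (0.40, adjusted p = 0.00158), and within slide 1 it read -0.01. Adjusted over the list alone the same number, 2 of 5, rose, and the list did not pass camera (adjusted p = 0.395, median log2 change 0.26 and 0.08 within slide 1).

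The other interferon regulatory factors moved in both directions, with 4 rising and 3 falling of 7 tested, and the same counts adjusted over the list alone. Irf9, the DNA-binding part of a complex that forms after interferon binds its receptor, was 5.48-fold higher (log2 change 2.46, SE 0.036). Irf5 rose by 0.88 (SE 0.054), Irf8 by 0.53 (SE 0.038) and Irf2 by 0.33 (SE 0.077). Irf3, a relative of Irf7 that also activates Ifnb1, fell by 0.70 (SE 0.031), and a second probe read -0.49. Irf3 lies on chromosome 7, whose 1129 tested genes outside the interferon and antigen presentation lists had a median log2 change of -0.38. Irf1 fell by 0.40 (SE 0.033), with -0.70 from a second probe, and Irf4 was not tested because it was not well above background on any array. The call of Irf1 ended without scaling between arrays (adjusted p = 0.0947). With slide as a block Irf2 read 0.36 and did not pass (adjusted p = 0.0565), while within slide 1 it did (adjusted p = 0.0399). As a list the family did not pass camera (adjusted p = 0.662, median 0.33 and 0.36 within slide 1).

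Sensors and signal carriers of the interferon system were split. Of 32 tested, 15 rose, 6 fell and 11 did not pass, and 17 rose and 7 fell when adjusted over the list alone. The largest rises among the named members belonged to the RNA sensor regulator Dhx58 (log2 change 2.64, SE 0.032), the RNA sensor Ifih1 (2.01, SE 0.039) and the signal carrier Stat2 (1.83, SE 0.032). The median member moved by 0.12, and 4 members also stand in the antiviral list. The list passed camera narrowly (adjusted p = 0.0412, and 0.797 with an estimated correlation). Its median was 0.12 with slide as a block and within slide 1, and quantile normalization (adjusted p = 0.0508) or leaving out base-vector replicate 1 (adjusted p = 0.0725), base-vector replicate 2 (adjusted p = 0.0598) or all chromosome 7 genes (adjusted p = 0.0818) ended the call. The list has 0 members on chromosome 7, so in the last case the genes it was compared with changed and the list did not.

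Of the genes that load and present peptides on MHC class I, more rose than fell. Of 25 tested, 20 rose, 4 fell and 1 did not pass, with the same counts adjusted over the list alone, and the median member was 1.35-fold higher (log2 change 0.43). Tapbp, which bridges the peptide transporter to class I molecules, rose by 1.01 (SE 0.033), the transporter subunit Tap1 by 0.77 (SE 0.036) and H2-T23 by 0.50 (SE 0.029). H2-T24 was below the detection limit in the base-vector cells and at least 2.13-fold higher in the IRF7 cells. Its fitted log2 change was 2.92 (limma adjusted p = 1.59e-06), and 0.83 with normexp. The list passed camera (adjusted p = 0.000606), with adjusted p = 0.797 with an estimated correlation, and its median was 0.44 with slide as a block and within slide 1. MHC class II genes were mostly too dim, with 4 of 14 tested, of which 2 rose and 1 fell (3 rose and 1 fell when adjusted over the list alone). Cd74, the invariant chain, was not well above background in the base-vector cells and at least 1.84-fold higher in the IRF7 cells, with a log2 change of 0.29 with normexp. The class II transactivator Ciita rose by 0.37 (SE 0.069), and did not pass within slide 1, at 0.32 with 1 base-vector array (adjusted p = 0.0528), or with normexp, at 0.06 (adjusted p = 0.299). H2-DMa fell by 0.18 (SE 0.035), with a log2 change of 0.02 where arrays were not scaled.

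Ligands and checkpoints read by natural killer and T cells moved both ways. Of 14 tested, 8 rose, 5 fell and 1 did not pass, with the same counts adjusted over the list alone. The death receptor Fas rose by 1.71 (SE 0.076, above background on 1 base-vector array, and 0.76 with normexp), and Lgals9, a galectin that also stands in the antiviral list, rose by 1.31 (SE 0.039). Fas lies at 30 to 40 Mb of chromosome 19, where 48 tested genes had a median log2 change of 0.34. Raet1a, a ligand of the activating receptor NKG2D, fell by 1.38 (SE 0.043), with -1.59 from its second probe. Nectin2, a ligand of the receptor DNAM-1, fell by 0.97 (SE 0.025) and lies on chromosome 7. The list did not pass camera (adjusted p = 0.462, median 0.38 and 0.36 within slide 1).

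Inflammatory cytokines and chemokines were higher in the IRF7 cells more often than lower. Of 21 tested, 15 rose, 3 fell and 3 did not pass, with the same counts adjusted over the list alone, and the median log2 change was 0.52. Il18 was 7.72-fold higher (log2 change 2.95, SE 0.030) and the granulocyte growth factor Csf3 5.83-fold higher (2.54, SE 0.044). Csf2 and Ccl20 were not well above background in the base-vector cells and were at least 1.92-fold and 1.52-fold higher in the IRF7 cells. With normexp their log2 changes were 0.57 and 0.37. The list passed camera (adjusted p = 0.0023), with adjusted p = 0.797 with an estimated correlation, and its median was 0.51 with slide as a block and within slide 1. NF-kB targets and regulators had no common direction, with 11 rising, 7 falling and 3 not passing of 21 (12 and 7 when adjusted over the list alone; camera adjusted p = 0.662, median 0.11 and 0.09 within slide 1). Ier3 rose by 1.54 (SE 0.036) and the prostaglandin synthase Ptgs2 by 1.10 (SE 0.034), while the adhesion molecule Vcam1 fell by 1.54 (SE 0.031) and Bcl3 by 1.17 (SE 0.028). All 3 members of that list on chromosome 7 fell, Bcl3 among them.

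Across all genes, 9429 of 15414 passed the threshold (61.2%), 4954 of them higher and 4475 lower in the IRF7 cells. The differences past the threshold had a median absolute log2 change of 0.35. At least 2-fold changes numbered 902, of which 510 were higher and 392 lower. In 174 of these a group was not well above background, and 93 of the 174 had a lower bound of at least 2-fold. The 3 arrays of a group all lay on 1 side of the other 3 in 10476 genes (68.0%), against 10% by chance. The log2 levels of any pair of arrays correlated across genes at 0.995 to 0.997 within a group and at 0.978 to 0.980 between groups. With slide as a block 7162 genes passed, 896 of them 2-fold, and within slide 1 7498 passed, 905 of them 2-fold. Slide 1 holds 1 base-vector array, so there the spread comes from the IRF7 arrays alone and the lone array is assumed to vary like them. Without scaling between arrays, 79.1% of the called genes were higher, against 52.5% in the scaled values, because the median log2 change of all genes moved from 0.03 to 0.23. With no filter on dim probes 14538 of 27670 genes passed and 33.0% of them were higher, and with normexp 516 genes changed 2-fold.

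**Figure D2:**
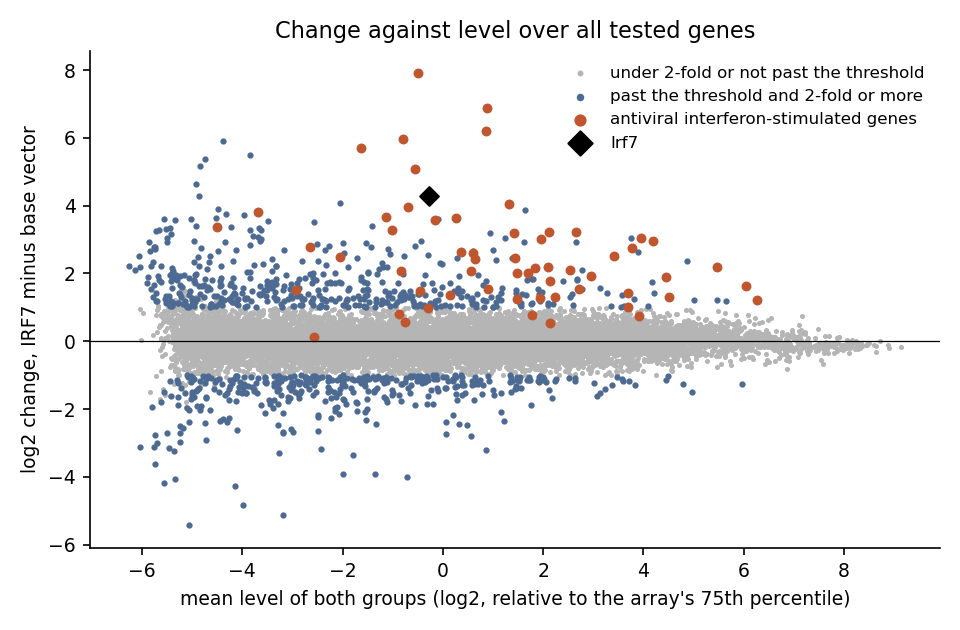
Log2 change (IRF7 minus base vector, vertical) against the mean log2 level of both groups relative to the array's 75th percentile (horizontal) for the 15414 tested genes, with the 902 genes changed 2-fold in blue, the 59 antiviral genes in orange and Irf7 as a black diamond. All but 1 of the antiviral genes lie above 0.5, and the 2-fold changes in either direction spread over dim and bright genes.

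The largest rises and falls were ranked by fitted change, so the rank of a gene with only a bound is uncertain. Of the 12 largest rises, 5 genes were outside the interferon lists, and none of these was well above background in the base-vector cells. Dsp, a desmosome protein of epithelial cells, was at least 13-fold higher, the zinc finger gene Zfp979 at least 16.4-fold, Spats2l at least 8.44-fold, the Wnt receptor Fzd1 at least 7.29-fold and the selenium carrier Selenop at least 5.76-fold. Their limma adjusted p, which tests the fitted change and not the bound, ranged from 2.68e-07 for Dsp to 2.23e-05 for Zfp979. Second probes, not above background in the base-vector cells either, gave lower bounds of 5.07-fold for Dsp and 2.04-fold for Spats2l. Fzd1 lies in the first 10 Mb of chromosome 5, where 38 tested genes had a median log2 change of 0.60. The largest falls included 6 genes that were not well above background in the IRF7 cells. Sat2 was at least 15.5-fold lower, the small proteoglycan Ogn at least 11.4-fold, Whrn at least 8.99-fold, the glutaminyl cyclase Qpct at least 4.62-fold, Pipox at least 4.19-fold and Crocc2 at least 3.00-fold. A second Whrn probe was at least 1.64-fold lower. With normexp the log2 changes of Dsp, Zfp979, Spats2l, Fzd1 and Selenop were 2.93, 2.93, 2.48, 2.26 and 1.74. Those of Sat2, Ogn, Whrn, Qpct, Pipox and Crocc2 were -2.62, -2.35, -2.46, -1.51, -1.46 and -1.22. All were smaller folds than the bounds of the same probes. Among genes measured in both groups, Gpc4, a heparan sulfate proteoglycan, fell by 4.00 (SE 0.055), Trp53i11 fell by 3.92 (SE 0.060), the laminin chain Lama4 fell by 3.91 (SE 0.074) and the cyclic nucleotide phosphodiesterase Pde2a fell by 3.34 (SE 0.056). Pde2a lies on chromosome 7, and its second probe read -1.04. Sirpa, a receptor for Cd47, fell by 5.12 (SE 0.63), and the channel Trpv2 by 3.30 (SE 0.55). Without IRF7 replicate 3 Sirpa read -4.37 and Trpv2 -3.89, and with normexp they read -3.23 and -2.12. Further probes of Sirpa were at least 2.68-fold and 2.42-fold lower. Sirpa and Trpv2 were above background on 2 of the 3 IRF7 arrays, and Trpv2 did not pass within slide 1, at -3.18 with 1 base-vector array (adjusted p = 0.0561).

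Epithelial genes did not move as a list. Of 18 tested, 7 rose and 5 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.854, median 0.10 and 0.02 within slide 1). Beside Dsp, the keratin Krt7 rose by 2.63 (SE 0.047), whereas Cldn7, a tight junction protein, was at least 4.76-fold lower and not detected in the IRF7 cells, and Jup fell by 0.78 (SE 0.041). Mesenchymal and matrix genes were as divided, with 6 rising, 6 falling and 10 not passing of 22 and the same counts adjusted over the list alone (camera adjusted p = 0.931). Their median was 0.05, the mean -0.02 and the median within slide 1 -0.04, so the signs differed. Zeb1, a repressor of epithelial genes, was at least 3.16-fold higher, from below detection. The collagen VI chain Col6a1 fell by 3.17 (SE 0.068), and the proteoglycan Dcn was at least 3.16-fold lower, below detection in the IRF7 cells.

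Genes linked to bone metastasis were higher more often than lower. Of 23 tested, 14 rose, 5 fell and 4 did not pass, with the same counts adjusted over the list alone, and the median log2 change was 0.27. The collagenases Mmp1a and Mmp13 rose by 1.92 (SE 0.041) and 1.55 (SE 0.076), the matrix protein Ccn2 by 1.15 (SE 0.058) and the stromelysin Mmp3 by 0.75 (SE 0.040). The list passed camera (adjusted p = 0.0334), with adjusted p = 0.797 with an estimated correlation, and its median was 0.28 with slide as a block and within slide 1. Without base-vector replicate 1 the adjusted p was 0.0545, and without chromosome 7 genes, of which the list holds 1, it was 0.0818.

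More stress response genes fell than rose. Of 28 tested members of the unfolded protein and integrated stress response, 17 fell, 5 rose and 6 did not pass, with the same counts adjusted over the list alone, and the median log2 change was -0.20 (-0.01 without scaling between arrays). Sesn2 fell by 1.13 (SE 0.031), with -0.56 from a second probe, and the transcription factors Atf5 and Ddit3 fell by 1.01 (SE 0.036) and 0.99 (SE 0.027). Trib3, a pseudokinase induced by that response, fell by 0.99 (SE 0.033). Atf5 lies on chromosome 7, as does 1 other member, which also fell. The list passed camera (adjusted p = 0.0119), with adjusted p = 0.797 with an estimated correlation and 0.0505 with no filter on dim probes, and its median was -0.21 with slide as a block and within slide 1. In the opposite direction, 19 of 28 genes of cholesterol and fatty acid synthesis rose, 4 fell and 5 did not pass, with the same counts adjusted over the list alone. Hsd17b7 rose by 1.57 (SE 0.058), Cyp51 by 0.90 (SE 0.027) and Msmo1 by 0.76 (SE 0.034), all enzymes of sterol synthesis, while Tm7sf2 fell by 1.10 (SE 0.061). Cyp51 lies in the same first 10 Mb of chromosome 5 as Fzd1. The median was 0.25, the camera adjusted p 0.0119 and 0.797 with an estimated correlation, and the median 0.26 with slide as a block and within slide 1.

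Ribosomal protein and housekeeping genes were slightly lower relative to the array's 75th percentile, with 17 falling, 5 rising and 8 not passing of 30 and the same counts adjusted over the list alone. Their median log2 change was -0.12, and 0.08 where arrays were not scaled, in both cases below the median of all genes (0.03 scaled and 0.23 unscaled). Rpl13a fell by 0.60 (SE 0.034) and the elongation factor Eef2 by 0.45 (SE 0.029), while Hprt rose by 0.63 (SE 0.040) and Pgk1 by 0.49 (SE 0.032). Rpl13a is on chromosome 7, and all 4 members there fell. The list passed camera (adjusted p = 0.0229), with adjusted p = 0.811 with an estimated correlation. It also did not pass with slide as a block (adjusted p = 0.0512, median -0.13), within slide 1 (adjusted p = 0.0671, median -0.13) or without chromosome 7 genes (adjusted p = 0.0698). Nor did it pass under quantile normalization (adjusted p = 0.299, median -0.03), unscaled (adjusted p = 0.285) or with no filter on dim probes (adjusted p = 0.127).

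Cell cycle genes, p53 targets and hypoxia genes did not pass camera. Of 43 cell cycle genes 19 rose and 11 fell (adjusted p = 0.617), with a median of 0.02, or -0.02 under quantile normalization. Rrm2 rose by 0.80 (SE 0.054), Cdc6 by 0.54 (SE 0.039) and Ccne1, on chromosome 7, by 0.52 (SE 0.033), while the spindle protein Nusap1 fell by 0.49 (SE 0.031). Second probes read smaller changes, of 0.29 for Cdc6, 0.31 for Ccne1 and -0.21 for Nusap1. Of 27 p53 targets and cell death genes 11 rose and 10 fell (adjusted p = 0.662), with a median of -0.01, or 0.18 without scaling. Perp, a desmosome-associated p53 target, was 7.45-fold higher (log2 change 2.90, SE 0.054), whereas Trp53inp1 fell by 1.48 (SE 0.034) and the cell death gene Bbc3, on chromosome 7, by 1.42 (SE 0.027). Of 29 hypoxia and glycolysis genes 17 rose and 8 fell (adjusted p = 0.14, median 0.18). Ankrd37 rose by 1.07 (SE 0.069), Ndrg1 by 1.04 (SE 0.033) and the glucose transporter Slc2a1 by 0.95 (SE 0.047). Ndrg1 lies at 60 to 70 Mb of chromosome 15, where 24 tested genes had a median log2 change of 0.46. Aldoc fell by 1.79 (SE 0.058) by its brighter probe. Its other probe, dim and above background on only 2 arrays of each group, read -0.06 and did not show the fall, which therefore rests on 1 probe. In these 3 lists the counts were the same when adjusted over the list alone, and the medians within slide 1 were 0.01, -0.05 and 0.17.

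Markers of other cell types were tested where they were detected. Of 21 macrophage, neutrophil and dendritic cell markers on the array 6 could be tested and 2 rose, Cd14 by 0.38 (SE 0.032) and Fcer1g by 0.67 (SE 0.14; 0.49 within slide 1, adjusted p = 0.105; 0.27 with normexp). Of 20 lymphocyte markers on the array 5 could be tested, and Lck alone passed (0.11, SE 0.031), with 0 passing when adjusted over the list alone and 0.12 within slide 1 (adjusted p = 0.112). Among 9 tested markers of fibroblasts, endothelium and fat cells, 3 rose and 3 fell, and the same counts held when adjusted over the list alone, as they did for the 2 myeloid genes. The platelet-derived growth factor receptors Pdgfra and Pdgfrb were lower, Pdgfra by 1.21 (SE 0.030) and Pdgfrb at least 2.89-fold with no IRF7 array above background. The endothelial receptor Tie1 rose by 1.57 (SE 0.062) and the endothelial cadherin Cdh5 by 1.06 (SE 0.038). These 3 lists did not pass camera (adjusted p = 0.307, 0.647 and 0.854, medians 0.28, 0.11 and 0.31). Within slide 1 the medians were 0.15, 0.02 and -0.03.

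**Figure D3:**
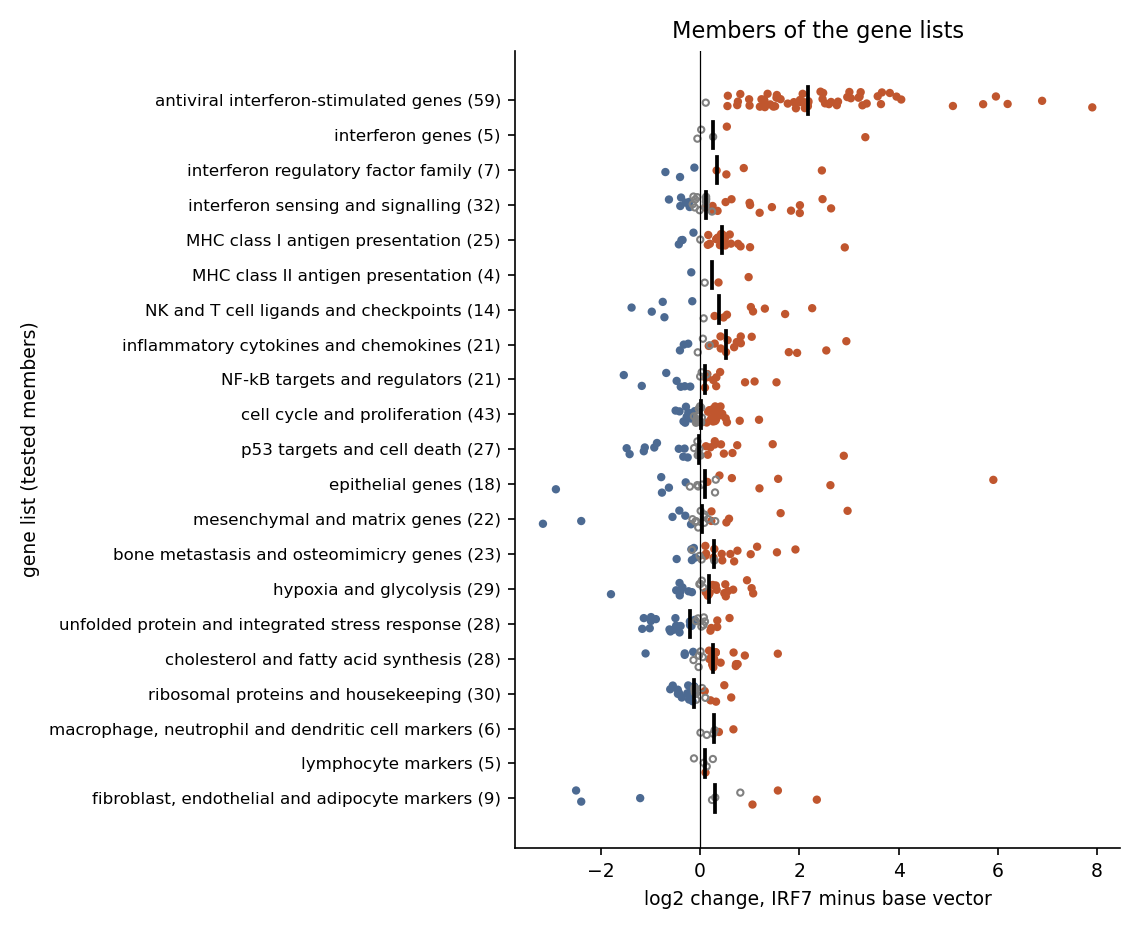
Log2 change (IRF7 minus base vector, horizontal) of each tested member of the 21 gene lists (vertical, with the number tested), with filled points for genes past the threshold (orange higher, blue lower), open grey points for genes that did not pass, random vertical scatter within a list and a black bar at the list's median. The antiviral genes have the highest median, 2.18, and the next highest, of the cytokines, is 0.52.

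Of the 20 lists with at least 5 tested members, 8 passed camera, 6 upward and 2 downward. None passed with an estimated correlation. In fry, which asks whether a list's genes move on balance in one direction and compares them with no other genes, 17 passed. Each named gene that passed had all 3 arrays of a group on 1 side of the other 3, which the naming rule required of the largest rises and falls.

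The position of genes on the chromosomes, examined after the data were seen, was related to their change. Chromosome 7 stood lowest of the autosomes and X, with a median log2 change of -0.38 over 1129 genes. In 1000 shuffles of the genes, 95% of the medians lay between -0.0013 and 0.0525 (permutation p = 0.001, the smallest the shuffles can give, and 0.002 adjusted). That p was shared by 10 of 20 chromosomes. Small shifts passed too, such as a median of 0.06 on chromosome 17 (permutation adjusted p = 0.039). The shuffles treat neighbouring genes as independent, so their p does not measure the spread between cultures or populations. On chromosome 7, 7.88% of genes were at least 2-fold lower, against 0.461 to 4.27% on the others. Chromosome 11 had a median of -0.14, made up of -0.24 over 788 genes in its first 90 Mb, which hold Sat2, Pipox, Trpv2, Cldn7, Aldoc and Irf1, all lower, and Lgals9 and Csf2, both higher, and -0.00 over the other 523, a division made after the values were seen. Chromosome 2 had a median of -0.12 and chromosome 1 of 0.15. The shift on chromosome 7 was seen in each IRF7 array, at -0.38, -0.38 and -0.38 against the base-vector mean. With slide as a block and within slide 1, the median on chromosome 7 was -0.39.

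**Figure D4:**
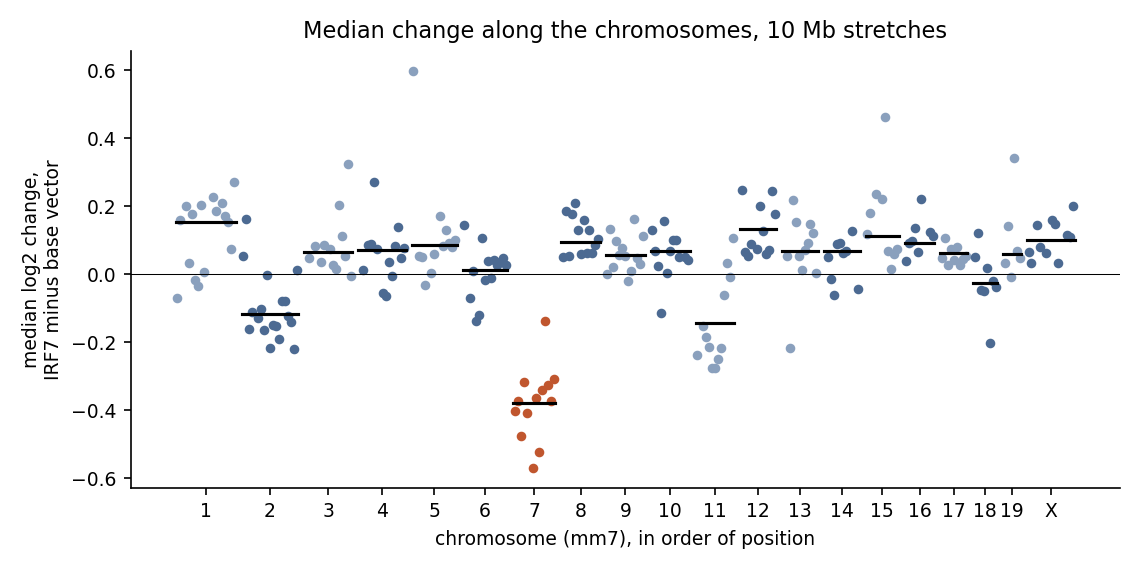
Median log2 change (IRF7 minus base vector, vertical) of the tested genes in 10 Mb stretches holding at least 20 genes (points) along the chromosomes of mm7 (horizontal, in order), with black lines at the medians of whole chromosomes and chromosome 7 in orange. All 13 stretches of chromosome 7 lie below 0, and the highest stretch, at 0.60, is the start of chromosome 5.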

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

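The loss of chromosome 7 genes was chosen after the data were seen; the other alternatives were planned. Irf7 stayed past the threshold with the same direction under all alternatives run on it, with a log2 change of 4.24 to 4.32 over the fits without 1 array. For the changes below the cause was not tested, except that fewer arrays or genes enter where arrays or genes are left out. Signal over background limits the dim genes: 257 tested genes were not well above background on any base-vector array and 52 on any IRF7 array.

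Counts of genes past the threshold moved by over 1.5 times with no filter on dim probes (14538, of which 9747 lower), with replicate and slide as blocks (5658, of which 2837 higher and 2821 lower), and unscaled (1701 lower and 241 lower 2-fold). With normexp, 516 genes changed 2-fold (284 higher, 232 lower). Without 1 array, 8310 to 9075 genes passed, 884 to 966 of them 2-fold. Without chromosome 7 genes 8574 passed.

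Shared replicate numbers were not taken to pair the samples: deviations of same-numbered samples correlated at 0.045, 0.175 and 0.229, not all over 0.1, though every sample correlated best with its own number, a hint from the data. With the replicate block 9780 genes passed, 9090 of them also called without it, and the sensing list had adjusted p = 0.0873.

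With an estimated correlation the adjusted p was 0.368 for antiviral genes, 0.797 for sensing, MHC class I, cytokines, bone metastasis, stress response and cholesterol synthesis, and 0.811 for ribosomal genes. The sensing list had 0.0508 under quantile normalization and 0.0818 without chromosome 7 genes, and 0.0273 to 0.0725 without 1 array. Bone metastasis genes had 0.0818 without chromosome 7 genes and 0.0273 to 0.0545 without 1 array. The stress response had 0.0505 with no filter on dim probes. Ribosomal genes had 0.299 under quantile normalization, 0.285 unscaled, 0.127 with no filter, 0.0811 with the mean of a gene's probes, 0.0512 with slide as a block, 0.0671 within slide 1, 0.172 with replicate and slide as blocks and 0.0698 without chromosome 7 genes. Calls were gained in fry for interferon genes (0.000362), interferon regulatory factors (0.000249), natural killer and T cell ligands (0.0221), cell cycle (0.0177), p53 (0.00482), epithelial (0.000184), hypoxia (0.00161) and myeloid genes (0.0031), and for hypoxia with no filter (0.00269). The fibroblast, endothelial and fat list was reversed in fry (downward, 0.00125). Among named genes, H2-DMa lost its call in unscaled values, with a log2 change of 0.0207 (limma adjusted p = 0.872). Apart from that, 30 calls of a named gene under an alternative were lost and 2 gained. The lymphocyte list had too few members to test without chromosome 7 genes.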

Other observations

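The tests of slide, scaling, gene families, fibroblasts, chromosome 7 copies and a response to Irf7 were chosen only after the result was seen, and the chromosomes were examined because of the data; the tests of other splits, of neighbouring genes and of probe GC content were written before.

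Among 355 gene families grouped by the stem of their symbols and outside the fixed lists, 6 passed camera, none with an estimated correlation (adjusted p of 0.345 to 0.981). The Slfn genes, which interferon induces, rose in 5 of 5 members with a median log2 change of 0.88, and 5 Ifi genes rose with a median of 2.26. All 9 Hoxa genes fell (median -0.45, and -0.25 unscaled), as did 11 of 15 Aldh genes (median -0.33, and -0.13 unscaled). Of 284 Zfp genes 156 fell and 38 rose (median -0.20, and -0.00 unscaled), with 73 of them on chromosome 7. Of 37 Rpl genes 21 fell and 1 rose (median -0.15), and unscaled the median was 0.05, below the median of all genes (0.03 scaled and 0.23 unscaled) in both.

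Changes were spread over far more genes than the interferon lists. Outside the interferon and antigen presentation lists 841 genes changed 2-fold. Over all genes, list members included, 8527 passed the threshold with a change under 2-fold. Slide was argued against as the cause of most of these changes, not of each. Genes were chosen without base-vector replicate 1, which is on the slide of the IRF7 arrays. In the median that array lay at 0.0163 of the way from the other base-vector arrays to the IRF7 mean for the larger changes and at 0.0359 for the smaller. It was nearer the IRF7 mean in 6.87% of the 903 larger and 9.24% of the 8109 smaller changes chosen so, where slide stays open. Of the smaller changes 52.1% were higher, a balance that the scaling sets and that decides nothing, but a constant per array leaves correlations as they are, and over genes changed by under 2-fold the highest between groups was 0.992, below the lowest within a group (0.996). Large DNA copy differences stay open, since 83.5% of the larger changes stayed 2-fold after the median of the 100 nearest genes was taken off and the median absolute change fell by 7.77%. Chance cannot be judged from 10 splits, of which 1, the real one, gave as many genes (9429, highest other 2), as many 2-fold genes (902, highest other 2) and as many lists (8, highest other 5), and an effect of Irf7 cannot be told apart from other differences between the 2 pooled populations.

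Genes on chromosome 7 read lower in the IRF7 cells, by -0.43 against the other chromosomes, by -0.28 with no filter on dim probes, and by -0.16 among the 377 dimmest genes against -0.49 and -0.48 among the middling and the bright. Probe GC content and level were argued against as the whole cause, with 96.6% of the shift left after they were taken off, and so was slide, with 95.4% left within slide 1. A lower copy number in the IRF7 population stays open, as no DNA was measured: 13 of 13 stretches of 10 Mb lay below 0, but the chromosome was picked for its low median. The stretches ran from -0.57 to -0.14, where 3 copies against 4 would give -0.415 (log2) and 1 copy against 2 would give -1. The number of copies in either population was not measured, so a value near 1 of these ratios decides nothing. The first 10 Mb of chromosome 5, with a median of 0.60 over 38 genes, hold Abcb1b (1.53), a drug efflux pump named after its values were seen. Both populations were selected with puromycin, and a link between that selection and the rise was not tested. A response of the chromosome to Irf7 stays open too, as 0 further populations with introduced Irf7 were measured.

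Of the mesenchymal and fibroblast lists, which as wholes moved both ways, Col6a1, Pdgfra, Pdgfrb and Dcn fell at least 2-fold in the IRF7 cells and were picked for that. Fibroblasts among the base-vector cells were tested first by the median log2 change of Col1a1, Col1a2 and Col3a1 (-0.84), which decides nothing, since the Col1a1 and Col3a1 probes were mostly not above background. A second measure was then chosen with the values in view, and found 0 of those 3 collagens above background on all 3 base-vector arrays, although a Col1a2 probe was above it on 2 of 3 base-vector and 3 of 3 IRF7 arrays. This argues against many fibroblasts but was picked after the first had not decided, so a small share of such cells may remain, and an effect of Irf7 or of the choice of clones was not tested apart.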
